A study of Drosophila melanogaster with 32 samples.

How the data were processed

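The samples were 32 libraries of polyadenylated RNA from heads of male Drosophila melanogaster, each a biological replicate of about 100 flies per the labels' protocols, from 4 strains named hsp70-1c, hsp70-4c, hsp70- and w+hsp70-. Flies were naive or had been trained, and trained flies were collected at 5 h or 24 h; the labels do not describe the training. Libraries were strand-specific and sequenced as 75-bp single-end reads per the labels' protocols. Per the submitters' processing notes, the authors trimmed the reads with Trimmomatic, aligned them with STAR 2.5.0a to build dm6 and counted them with featureCounts 1.5.0-p1. The deposited files hold raw counts, that is whole numbers of reads per gene, in 1 file per library; their settings, strand setting and annotation release are not stated. Each file had 17559 genes and 12 further lines of read-status totals, and in 32 of 32 files the genes summed to the total of assigned reads. Of the gene identifiers, 17253 had a symbol in the reference table and 306 had none. Positions come from the Ensembl BDGP6 annotation, which uses dm6 coordinates.

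Groups were taken from the sample titles, with 3 or 4 replicates in each of 10 groups of strain and time. The titles of the naive hsp70-4c libraries read as a control for 5 h, and they were used as naive, as their other labels state. Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter on the groups in the fit, a group-means model, robust quasi-likelihood tests, 2-sided, and Benjamini-Hochberg adjustment over the genes tested, with an adjusted p under 0.05 called and no minimum fold. Training comparisons used all libraries of a strain, naive strain comparisons the naive libraries of the 4 strains, and differences between responses an interaction contrast. Standard errors (SE) of log2 changes come from the same fit. The p-values measure variation between replicate pools of flies. CPM (counts per 1e+06 reads) of a gene beside its test use TMM effective library sizes of that fit. Those plotted, summed over a gene list or given for a strain over all times use TMM effective sizes over all 32 libraries, and those of the Hsp70 permutation tests use the assigned reads of the library. Errors written with ± are standard deviations (SD) over the replicates of a group.

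Before the data were examined, 27 gene lists were fixed, covering chaperones, immunity, neurons and memory, senses, metabolism, and cell types that a head sample could hold. A list with 3 or more tested members was compared with all other genes by limma 3.58.1 camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of the comparison. The same test was run with a correlation estimated for each list, and fry tested whether a list's genes moved one way on balance. The summed CPM of the 6 inducible Hsp70 genes was compared between naive strains with exact 2-sided permutation tests on log2(CPM + 1), adjusted over 3 pairs of groups (Python 3.11.15, SciPy 1.17.1, NumPy 2.4.6, pandas 2.3.3). Overlaps of calls between strains, which share no library, were tested with Fisher's exact test. Figures were drawn with matplotlib 3.10.9.

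The genes, lists, tests, alternatives and the rule for named genes were chosen before the data were examined; tests chosen later are named where they appear. The named genes are the Hsp70 genes; for each comparison of 2 groups, up to 8 called genes in each direction with the largest changes, at least 5 CPM in the higher group and no overlap between libraries; up to 5 in each direction for an interaction; up to 4 members of each list with the smallest p; and up to 10 genes changed in 3 or more strains at 5 h. The text gives a part of them. A gene at 0 in every library of a group is given as at least so many fold higher, against a floor of 3 counts summed over that group. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules.

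Alternatives were DESeq2 1.42.0 size factors, no filter on low counts, all 32 libraries in 1 fit, a replicate block, the DESeq2 Wald test, and leaving out each library in turn. The method was tested on simulated data with the depth and spread of these libraries and 200 changed genes. At 5 h it recovered 79.1% of 2-fold changes in hsp70-1c, 86.6% in hsp70-4c, 70.1% in hsp70- and 91% in w+hsp70-; of 1.5-fold changes it recovered 41.8%, 43.3%, 16.4% and 37.3%. False calls made up 5.4%, 3.2%, 10.7% and 8% of the calls in the same order. For the naive hsp70-4c and hsp70-1c comparison it recovered 88.1% of 2-fold changes, and for the difference of their 5 h responses 65.7%. The simulated genes varied independently of each other, without shifts shared by many genes of a library, so recovery in the real data can be lower. Lists with under 3 tested members had no list test, and raw reads were not used here.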

Results

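RNA from heads of male flies was sequenced in 32 libraries from 4 strains. Per the series labels the study concerns hsp70 in the forming of memory, so naive strains were compared with each other and trained flies with naive flies of their strain. Strain hsp70-1c had 4 naive libraries, 3 at 5 h after training and 3 at 24 h, and hsp70-4c had the same numbers. Strains hsp70- and w+hsp70- each had 3 naive libraries and 3 at 5 h. Assigned reads per library, in units of 1e+06 reads, ranged from 4.54 to 10.34 with a median of 7.38. In hsp70-1c they were 5.1 to 10.02 in naive flies, 7.88 to 10.34 at 5 h and 6.67 to 8.11 at 24 h. In hsp70-4c they were 7.48 to 8.61, 7.02 to 8.26 and 7.0 to 7.88 at the same times. In hsp70- they were 4.54 to 5.17 in naive flies and 5.61 to 7.77 at 5 h, and in w+hsp70- 5.54 to 6.8 and 6.17 to 6.92. Between 12642 and 14205 genes had a read in a library.

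The inducible Hsp70 genes, which encode the heat-induced chaperone, had reads in hsp70-4c and few in the other strains. Hsp70Bc (chromosome 3R, 12509076 to 12511461) had 21 to 54 counts in each of the 10 hsp70-4c libraries, at 4.45 ± 0.957 CPM. It had 3 counts in 1 hsp70-1c library (naive replicate 3), 0 in the other hsp70-1c libraries and 0 in the 12 libraries of hsp70- and w+hsp70-. Hsp70Aa had 0 to 3 counts in any library, and Hsp70Ab, Hsp70Ba, Hsp70Bb and Hsp70Bbb had 0 in all 32. The copies are nearly identical, so reads shared between them may not have been counted, which was not tested, and the level of a single copy is uncertain. Summed over the 6 genes, naive flies had 5.24 ± 0.796 CPM in hsp70-4c (n = 4) and 0.204 ± 0.236 in hsp70-1c (n = 4), a log2 difference of 2.39 (exact permutation test, p = 0.0286, the smallest that 70 arrangements allow, adjusted p = 0.0429). The naive hsp70- and w+hsp70- libraries together had 0.0301 ± 0.0737 CPM (n = 6) against 2.72 ± 2.75 in hsp70-1c and hsp70-4c together (n = 8, log2 difference -1.40, exact permutation p = 0.0243, adjusted p = 0.0429). Both adjusted p were 0.0559 without hsp70-1c naive replicate 2 or 3 and 0.0804 without any of hsp70-4c naive replicates 1 to 4 (exact permutation tests). The test of hsp70- and w+hsp70- together pooled libraries of different strains on each side, so its p does not measure variation between strains. Between w+hsp70- (0.0602 ± 0.104 CPM) and hsp70- (0 CPM) no difference was detectable at this depth (n = 3 each, exact permutation p = 1, smallest possible 0.1). The white gene w, an eye pigment transporter, had 0.169 ± 0.131 CPM in hsp70- (n = 6), 7.65 ± 1.58 in hsp70-1c (n = 10), 29.8 ± 4.96 in hsp70-4c (n = 10) and 80.1 ± 9.51 in w+hsp70- (n = 6).

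**Figure D1:**
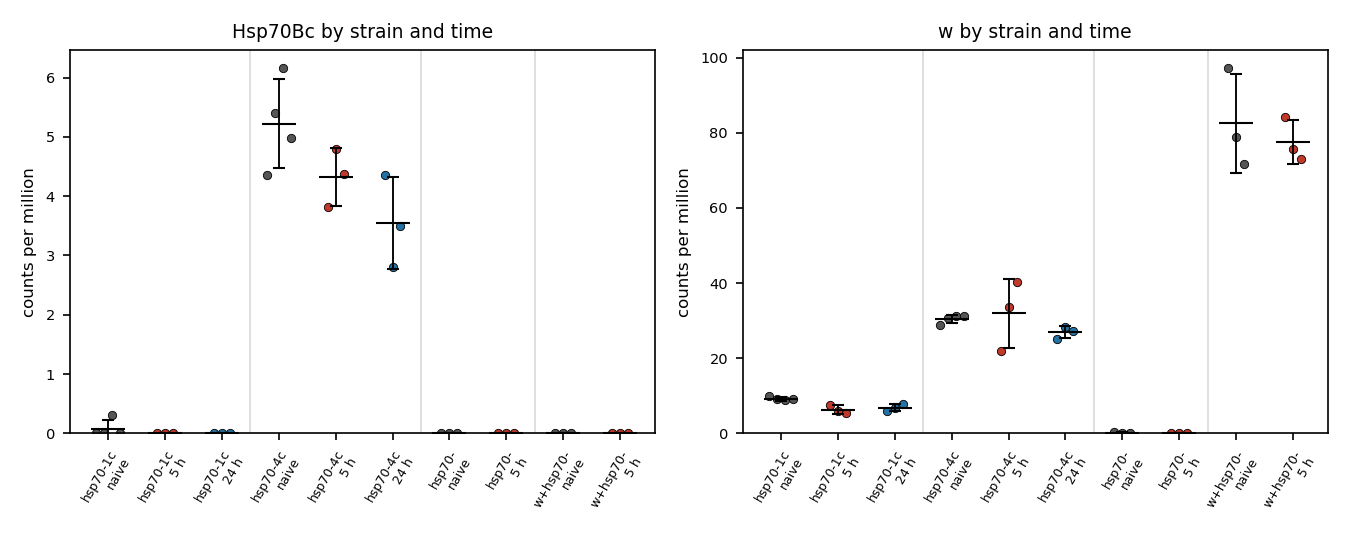
CPM of Hsp70Bc (left) and w (right) in each library by strain and time. Points are libraries, bars the mean ± SD. Hsp70Bc was at 4.45 ± 0.957 CPM over the hsp70-4c libraries, and w was lowest in hsp70- and highest in w+hsp70-.

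Naive hsp70-4c and hsp70-1c flies differed in 1058 of 10462 tested genes, 441 higher and 617 lower in hsp70-4c. Rh6, a photoreceptor opsin, was at 21.5 ± 2.42 CPM in hsp70-4c and 440.6 ± 13.2 in hsp70-1c (log2 difference -4.36, SE 0.11, n = 4 each), and Cyp6a17, a cytochrome P450, differed by -9.37 (SE 0.25). Octbeta3R, an octopamine receptor gene that starts just past Hsp70Bc on 3R (12511570 to 12548229), was at 17.9 ± 1.26 CPM in hsp70-4c and 0.0256 ± 0.0511 in hsp70-1c. The genes mthl8 and GluRIB, a glutamate receptor gene, had no read in naive hsp70-1c and were at least 181-fold and 122-fold higher in hsp70-4c; CG43291 had none in hsp70-4c and was at least 65.1-fold lower there. The larval serum proteins went both ways: Lsp1alpha by -4.45 (SE 0.43) and Lsp1beta by -2.70 (SE 0.40), Lsp1gamma by 6.42 (SE 0.60).

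Of 22 antimicrobial peptide genes, 9 were lower in hsp70-4c than in hsp70-1c, 0 higher and 13 did not pass. Adjusted over the list alone, 12 were lower. Def, a defensin, differed by -2.57 (SE 0.47), and the median log2 difference of the list was -1.86 (adjusted p = 1.14e-07 and adjusted p = 0.352 with an estimated correlation). Phototransduction genes had 2 higher and 10 lower of 27 (2 and 11 adjusted over the list alone, adjusted p = 0.00247 and adjusted p = 0.136 with an estimated correlation); Rh4 differed by -0.47 (SE 0.09) and Rh3 by 0.47 (SE 0.09). Among 14 haemocyte genes 1 was higher and 6 lower, among them Hml at -0.58 (SE 0.10) and NimC1 at -0.52 (SE 0.11) (2 and 7 adjusted over the list alone, adjusted p = 0.0106 and adjusted p = 0.136 with an estimated correlation). Of 17 fat body genes of the head, 1 was higher and 4 lower (1 and 7 adjusted over the list alone, adjusted p = 0.0106 and adjusted p = 0.565 with an estimated correlation). Muscle genes had 4 higher of 25, among them Mhc, the myosin heavy chain, at 0.29 (SE 0.09) (10 adjusted over the list alone, adjusted p = 0.0209 and adjusted p = 0.979 with an estimated correlation). Chaperones other than inducible Hsp70 had 2 lower of 21, Hsc70-2 at -3.93 (SE 0.19) and Hsp68 at -0.99 (SE 0.17) (6 adjusted over the list alone, adjusted p = 0.027 and adjusted p = 0.716 with an estimated correlation). Fry passed 4 of 25 lists here, among them phototransduction (adjusted p = 5.85e-07), antimicrobial peptides and other chaperones (0.012 each). Strain, genetic background and any batch coincide here and cannot be told apart.

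Naive w+hsp70- and hsp70- flies differed in few genes, w first. It was at 82.6 ± 13.6 CPM in w+hsp70- and 0.205 ± 0.203 in hsp70- (log2 difference 8.53, SE 0.26, n = 3 each). Arp53D, an actin-related protein gene, had no read in hsp70- and was at least 52.0-fold higher in w+hsp70-. The noncoding RNA lncRNA:mimi was higher by 1.54 (SE 0.14) and retinin, a corneal lens protein gene, by 0.83 (SE 0.13), while se, an eye pigment enzyme gene, was lower, at -0.79 (SE 0.13). In all, 30 of 10462 genes differed, 22 higher and 8 lower. Odorant-binding protein genes had 0 called (8 higher adjusted over the list alone), with a median of 0.13 (adjusted p = 0.0169 and adjusted p = 0.968 with an estimated correlation). Chemoreceptor genes had 0 called of 66 (median 0.23, adjusted p = 0.0354 and adjusted p = 0.591 with an estimated correlation). Courtship genes had 0 called of 26 (median 0.11, adjusted p = 0.0354 and adjusted p = 0.23 with an estimated correlation, fry adjusted p = 0.0307). The count moved with single libraries: it was 14 without w+hsp70- naive replicate 1, 19 without w+hsp70- naive replicate 2, 52 without hsp70- naive replicate 1, 13 without hsp70- naive replicate 2 and 12 without hsp70- naive replicate 3, and DESeq2 called 48.

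The naive hsp70- and w+hsp70- strains together, compared with the mean of hsp70-1c and hsp70-4c, differed in 1610 genes, 648 higher and 962 lower. In 306 of the 1610 the libraries of the 2 sides did not overlap, as in 309 of the 10462 tested genes. Of 35 odorant-binding protein genes 2 were higher and 17 lower (3 and 20 adjusted over the list alone), Obp19a by -1.36 (SE 0.12) and Obp56h by -1.08 (SE 0.11). The median was -0.36 (adjusted p = 2.59e-06 and adjusted p = 0.345 with an estimated correlation). Of 66 chemoreceptor genes 1 was higher and 17 lower (3 and 18 adjusted over the list alone), including Orco, the odorant co-receptor, at -0.87 (SE 0.10) (adjusted p = 0.000375 and adjusted p = 0.156 with an estimated correlation). Of 17 fat body genes 1 was higher and 10 lower (1 and 11 adjusted over the list alone), with Lsp2, a storage protein gene, at -3.19 (SE 0.47) (adjusted p = 7.69e-05 and adjusted p = 0.156 with an estimated correlation). Detoxification genes had 8 higher and 40 lower of 127 (10 and 48 adjusted over the list alone, adjusted p = 0.00011 and adjusted p = 0.156 with an estimated correlation). Phototransduction genes had 10 higher and 2 lower of 27 (11 and 5 adjusted over the list alone), Rh6 by 2.43 (SE 0.07) and ninaE, the main opsin gene, by 0.40 (SE 0.08) (adjusted p = 0.0045 and adjusted p = 0.156 with an estimated correlation). The memory gene rut, an adenylyl cyclase, was higher by 1.23 (SE 0.16), and ry, xanthine dehydrogenase, lower, at -1.55 (SE 0.07). By fry 8 of 25 lists passed. The p-values measure variation between replicate pools within strains and not variation between strains. They thus do not show that the strains without a 1c or 4c name differ as a kind from the others. Strain, genetic background and any batch coincide here too. Since hsp70-1c and hsp70-4c differ from each other, their mean stands for neither. Rh6 is such a case: it differed by -4.36 between hsp70-4c and hsp70-1c, so its 2.43 here includes the low level in hsp70-4c.

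**Figure D2:**
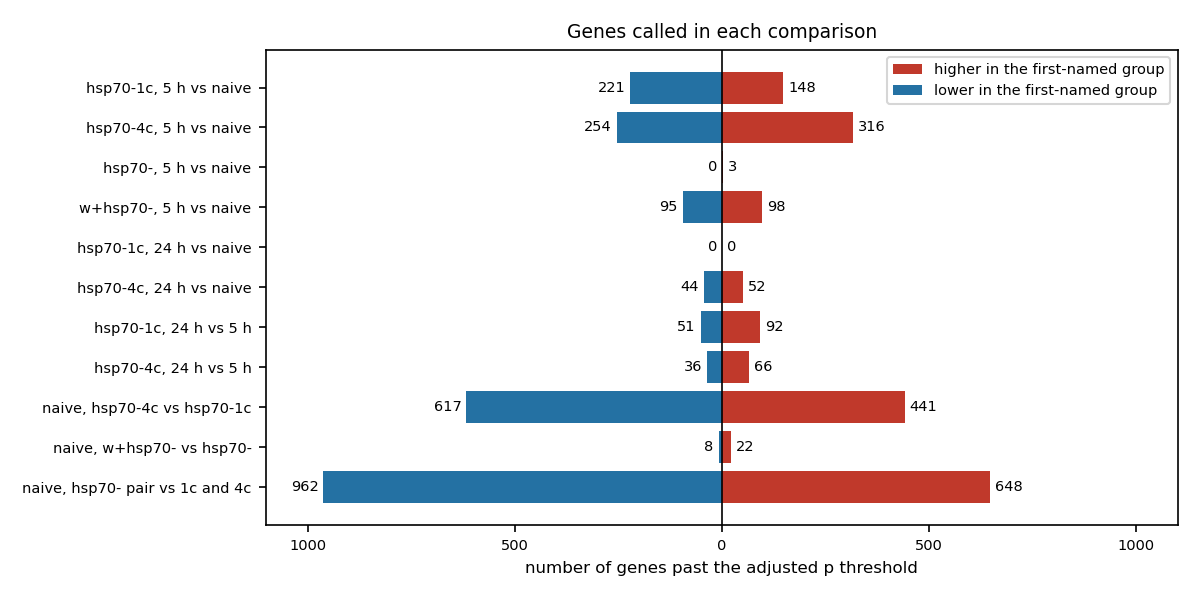
Number of genes past the adjusted p threshold in each comparison of groups, those higher in the first-named group to the right and those lower to the left. Strain comparisons called up to 1610 genes, training comparisons up to 570, and hsp70-1c at 24 h 0.

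In hsp70-1c flies 5 h after training, 369 of 10514 genes changed, 148 higher and 221 lower. Nep7, a neprilysin-like peptidase gene, rose from 7.28 ± 2.39 CPM (n = 4) to 34.8 ± 7.72 (n = 3), a log2 change of 2.23 (SE 0.25). MsrA, a methionine sulfoxide reductase gene, rose by 1.54 (SE 0.18) and Gnmt, glycine N-methyltransferase, by 1.43 (SE 0.22), while Sodh1, sorbitol dehydrogenase, changed by -1.77 (SE 0.14) and TotX, a stress-induced humoral factor, by -1.70 (SE 0.22). The antisense RNA asRNA:CR45485 was at -1.69 (SE 0.13), which is uncertain because the strand setting is not stated. The count of changed genes was 180 without 5h replicate 2 and 193 without naive replicate 4.

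Activity-regulated genes had 4 higher of 16, 0 lower and 12 not passing (6 higher adjusted over the list alone), among them Hr38, an immediate-early nuclear receptor, at 0.98 (SE 0.15), and puc, a phosphatase gene, at 0.70 (SE 0.11) (adjusted p = 2.18e-05 and adjusted p = 0.192 with an estimated correlation). Muscle genes had 3 lower of 25 (12 adjusted over the list alone), Act79B and Mlc1 by -0.48 (SE 0.10) and -0.47 (SE 0.11). All 25 log2 changes were negative (median -0.29, adjusted p = 3.02e-08 and adjusted p = 0.441 with an estimated correlation). In hsp70-1c the share of reads outside annotated genes was 66.8 ± 1.40% in naive libraries, 63.6 ± 1.26% at 5 h and 65.0 ± 0.90% at 24 h. Circadian genes had 2 higher, cwo by 0.79 (SE 0.15) and Pdp1 by 0.71 (SE 0.17), and 2 lower, cry by -0.42 (SE 0.10) and Ugt35B1 by -0.84 (SE 0.19), of 19 (8 and 3 adjusted over the list alone, adjusted p = 0.0259 and adjusted p = 0.28 with an estimated correlation). Detoxification genes went both ways, 6 higher and 9 lower of 127 (9 and 16 adjusted over the list alone): Cyp12d1-p by 1.69 (SE 0.25) and Cyp28d1 by -0.43 (SE 0.07) (adjusted p = 0.0232 and adjusted p = 0.441 with an estimated correlation). Fat body genes had 2 higher and 4 lower of 16 (3 and 5 adjusted over the list alone), with AkhR, the adipokinetic hormone receptor, at -0.77 (SE 0.11) and apolpp, a lipid carrier, at -0.49 (SE 0.08) (adjusted p = 0.0362 and adjusted p = 0.441 with an estimated correlation). Other chaperones had 2 higher of 21, Hsc70-5 by 0.35 (SE 0.07) and Hsc70-4 by 0.27 (SE 0.07) (4 adjusted over the list alone, adjusted p = 0.0362 and adjusted p = 0.441 with an estimated correlation). Antimicrobial peptides had 1 higher of 24, and ribosomal protein genes 2 higher of 79 (1 and 1 adjusted over the list alone, adjusted p = 0.00189 and 0.0232 and adjusted p = 0.462 and 0.75 with an estimated correlation). Single libraries ended some of these list calls. Without 5h replicate 3 the adjusted p was 0.0543 for circadian, 0.106 for fat body, 0.0539 for detoxification and 0.0901 for both chaperone and ribosomal protein genes, and without 5h replicate 1 it was 0.162 for detoxification and for chaperones. For fat body genes it was 0.0659, 0.0818 and 0.0590 without naive replicates 1, 3 and 4, for chaperones 0.125 and 0.0921 without naive replicates 3 and 4, and for ribosomal protein genes 0.0833 without 5h replicate 2 and 0.155 and 0.167 without naive replicates 2 and 3.

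Gut enzyme genes had 1 lower of 48 (1 adjusted over the list alone) with a median of -0.98 (adjusted p = 3.24e-06 and adjusted p = 0.462 with an estimated correlation), and their summed level was 38229 CPM in hsp70-1c naive replicate 2 against 9481 to 21255 in the other naive libraries of the strain. Testis genes had 0 called of 19 (0 adjusted over the list alone, median 1.38, adjusted p = 0.0322 and adjusted p = 0.692 with an estimated correlation). Their summed level was 171 CPM in hsp70-1c 5h replicate 2, and the adjusted p was 0.806 without that library, 0.0631 without naive replicate 2 and 0.0921 without naive replicate 4. Fry, which asks whether a list moves one way on balance, passed the activity-regulated and circadian lists (both adjusted p = 0.00455).

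In hsp70-4c flies 5 h after training, 32 of 80 ribosomal protein genes were higher, 0 lower and 48 did not pass (55 higher adjusted over the list alone), RpS27 by 0.45 (SE 0.07) and RpL29 by 0.44 (SE 0.07); 78 of 80 log2 changes were positive (median 0.25, adjusted p = 7.04e-23 and adjusted p = 0.327 with an estimated correlation). Of 25 muscle genes 11 were lower and 14 did not pass (17 lower adjusted over the list alone), Act57B by -0.69 (SE 0.12) and Mhc by -0.50 (SE 0.09). All 25 log2 changes were negative (median -0.56, adjusted p = 3.28e-12 and adjusted p = 0.327 with an estimated correlation). Of 22 antimicrobial peptide genes 6 were higher (16 higher and 1 lower adjusted over the list alone), the Bomanins BomS1 by 0.72 (SE 0.11) and BomS3 by 0.66 (SE 0.12) (median 0.86, adjusted p = 7.12e-09 and adjusted p = 0.327 with an estimated correlation). Neuropeptide genes had 1 higher, Tk (tachykinin) by 0.35 (SE 0.08), and 1 lower, Nplp4 by -0.90 (SE 0.16), of 36 (3 and 1 adjusted over the list alone, adjusted p = 0.00582 and adjusted p = 0.327 with an estimated correlation, adjusted p = 0.0667 without 5h replicate 2). Fry passed the ribosomal list (adjusted p = 0.00986) and the muscle, antimicrobial peptide and neuropeptide lists (0.0195 each). It also passed the circadian list (0.0317), which camera did not (adjusted p = 0.094).

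Single genes in hsp70-4c at 5 h included Gnmt, which rose from 42.2 ± 16.7 CPM (n = 4) to 496.5 ± 222.5 (n = 3), a log2 change of 3.56 (SE 0.52), and Nep7, which rose by 2.26 (SE 0.20). The gene fit, a fat body gene, rose by 1.81 (SE 0.32), Sodh1 changed by -1.74 (SE 0.22) and fru, a courtship transcription factor gene, by -1.01 (SE 0.24). Hsp70Bc was at 4.28 ± 0.504 CPM at 5 h and 5.17 ± 0.755 in naive flies (log2 change -0.28, SE 0.20), which did not pass (adjusted p = 0.436). Of 10400 genes 570 changed, 316 higher and 254 lower. The count was 205 without 5h replicate 2, 235 without 5h replicate 3, 247 without naive replicate 1, 319 without naive replicate 2 and 270 without naive replicate 3. Reads outside annotated genes made up 67.4 ± 1.01% in naive hsp70-4c libraries and 65.2 ± 1.18% at 5 h.

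**Figure D3:**
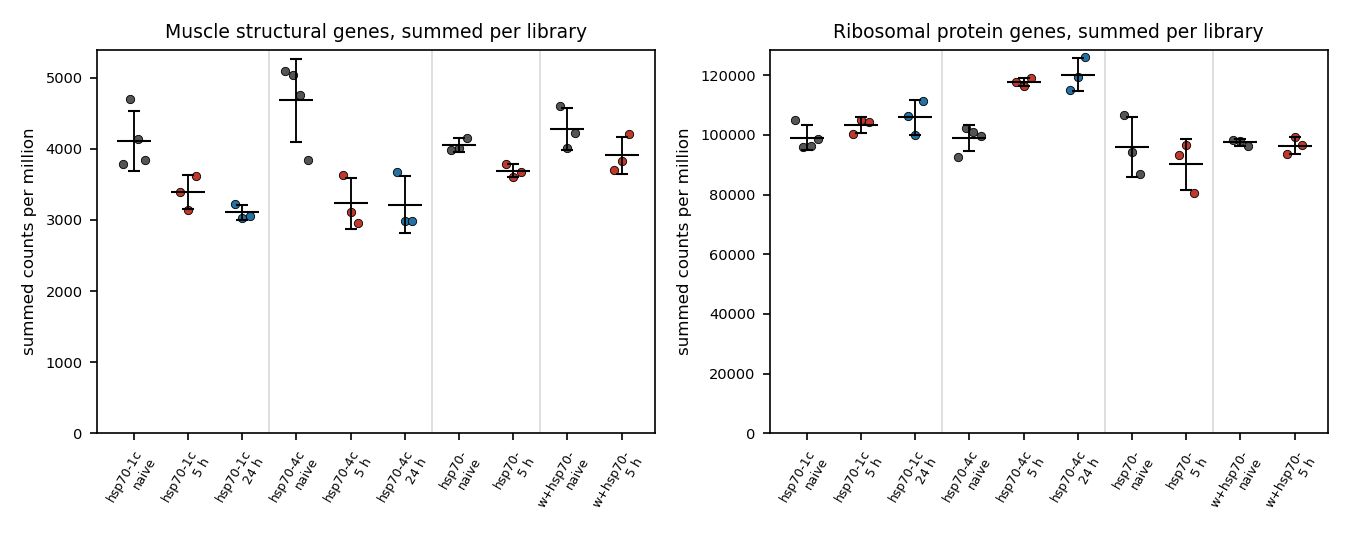
Summed CPM of the muscle genes (left) and the ribosomal protein genes (right) in each library by strain and time. Points are libraries, bars the mean ± SD. In hsp70-4c the muscle sum was 4683 ± 583 in naive flies and 3232 ± 359 at 5 h, and the ribosomal sum 98900 ± 4373 and 117560 ± 1325.

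In hsp70- flies 5 h after training, 3 genes passed, all higher: AttA, an antimicrobial peptide, from 10.4 ± 2.65 to 39.2 ± 4.14 CPM (log2 change 1.92, SE 0.18), CG15282 by 1.26 (SE 0.12) and Cyp6w1 by 1.10 (SE 0.11), n = 3 each. The tests covered 9849 genes, of which 621 had an unadjusted p under 0.05, and DESeq2 called 39. A larger change, that of Gnmt by 2.45 (SE 0.38, adjusted p = 0.223), did not pass, so few calls do not show a lack of response. The count was 12 without naive replicate 1, 0 without naive replicate 2, 17 without naive replicate 3, 0 without 5h replicate 1 and 13 without 5h replicate 3. Of 24 lists 9 passed with small medians, among them the protein-coding genes of the mitochondrial genome (0 called of 13, 1 lower adjusted over the list alone, median -0.25, adjusted p = 1.58e-05 and adjusted p = 0.529 with an estimated correlation) and the hormone list (0 called of 23, 2 higher adjusted over the list alone, median 0.28, adjusted p = 0.00101 and adjusted p = 0.458 with an estimated correlation). Muscle genes had 0 called of 25 (median -0.13, adjusted p = 0.00397 and adjusted p = 0.458 with an estimated correlation). The list of cAMP and memory genes (0 called of 48, median 0.13, adjusted p = 0.0313) and that of synaptic genes (0 called of 22, median 0.19, adjusted p = 0.0368) both had an adjusted p of 0.858 with an estimated correlation, and both changed direction without naive replicate 1 (adjusted p = 0.535 and 0.722). Without 5h replicate 3 they had 0.360 and 0.401.

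In w+hsp70- flies 5 h after training, 193 of 10015 genes changed, 98 higher and 95 lower. GstE3, a glutathione transferase gene, rose by 1.02 (SE 0.10) and GstE7 by 0.82 (SE 0.11). Among 122 detoxification genes 11 were higher and 5 lower (18 and 7 adjusted over the list alone, adjusted p = 0.266). CG5966, a lipase gene, rose from 18.9 ± 0.825 to 79.3 ± 6.02 CPM (log2 change 2.07, SE 0.11, n = 3 each), Hsp83, the Hsp90 chaperone, rose by 0.66 (SE 0.10), and Acer and AkhR changed by -1.18 (SE 0.09) and -1.14 (SE 0.11). Activity-regulated genes had 2 higher of 16 (3 higher and 1 lower adjusted over the list alone), sr by 1.39 (SE 0.26) and CG14186 by 0.59 (SE 0.13) (adjusted p = 0.00582 and adjusted p = 0.731 with an estimated correlation). Gut enzyme genes had 0 called of 45 with a median of 0.35 (adjusted p = 0.00198 and adjusted p = 0.731 with an estimated correlation, adjusted p = 0.119 without naive replicate 2), and muscle genes 0 called of 25 (1 lower adjusted over the list alone, median -0.14, adjusted p = 0.00257 and adjusted p = 0.731 with an estimated correlation). The count of changed genes was 95 without naive replicate 1, 123 without 5h replicate 3, 107 with all 32 libraries in 1 fit and 468 with no filter on low counts.

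Several genes changed alike at 5 h in most strains. Of 9733 genes tested in all 4 strains, 25 were higher and 17 lower in 3 or more, and Cyp6w1 passed in all 4. Nep7 changed by 2.23, 2.26, 0.89 and 1.25 in hsp70-1c, hsp70-4c, hsp70- and w+hsp70-, Gnmt by 1.43, 3.56, 2.45 and 2.76, Sodh1 by -1.77, -1.74, -1.09 and -1.16, and TotX by -1.70, -1.10, -1.42 and -1.47. The values in hsp70- did not pass. All but 1 of the 42 (CG9733, -0.07 in hsp70-) had the same sign in all 4 strains. Calls of hsp70-1c and hsp70-4c shared 55 higher genes where 4.50 were expected by chance (Fisher's exact test, adjusted p = 1.27e-45) and 66 lower genes where 5.40 were expected (adjusted p = 2.78e-54). Calls of hsp70-1c and w+hsp70- shared 41 and 49 (1.44 and 2.09 expected, adjusted p = 2.62e-50 and 3.70e-56), and those of hsp70-4c and w+hsp70- 39 and 21 (3.08 and 2.36 expected, adjusted p = 3.46e-33 and 1.93e-14). Fisher's exact test takes genes as independent, which genes that change together are not, so these p-values can be too small. Across genes, which are not independent replicates, log2 changes of hsp70-1c and hsp70-4c had a Pearson r of 0.526 and a Spearman rho of 0.476. This was the highest of the strain pairs. In the others r ran from 0.123 (hsp70-1c and hsp70-) to 0.456 (hsp70- and w+hsp70-).

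**Figure D4:**
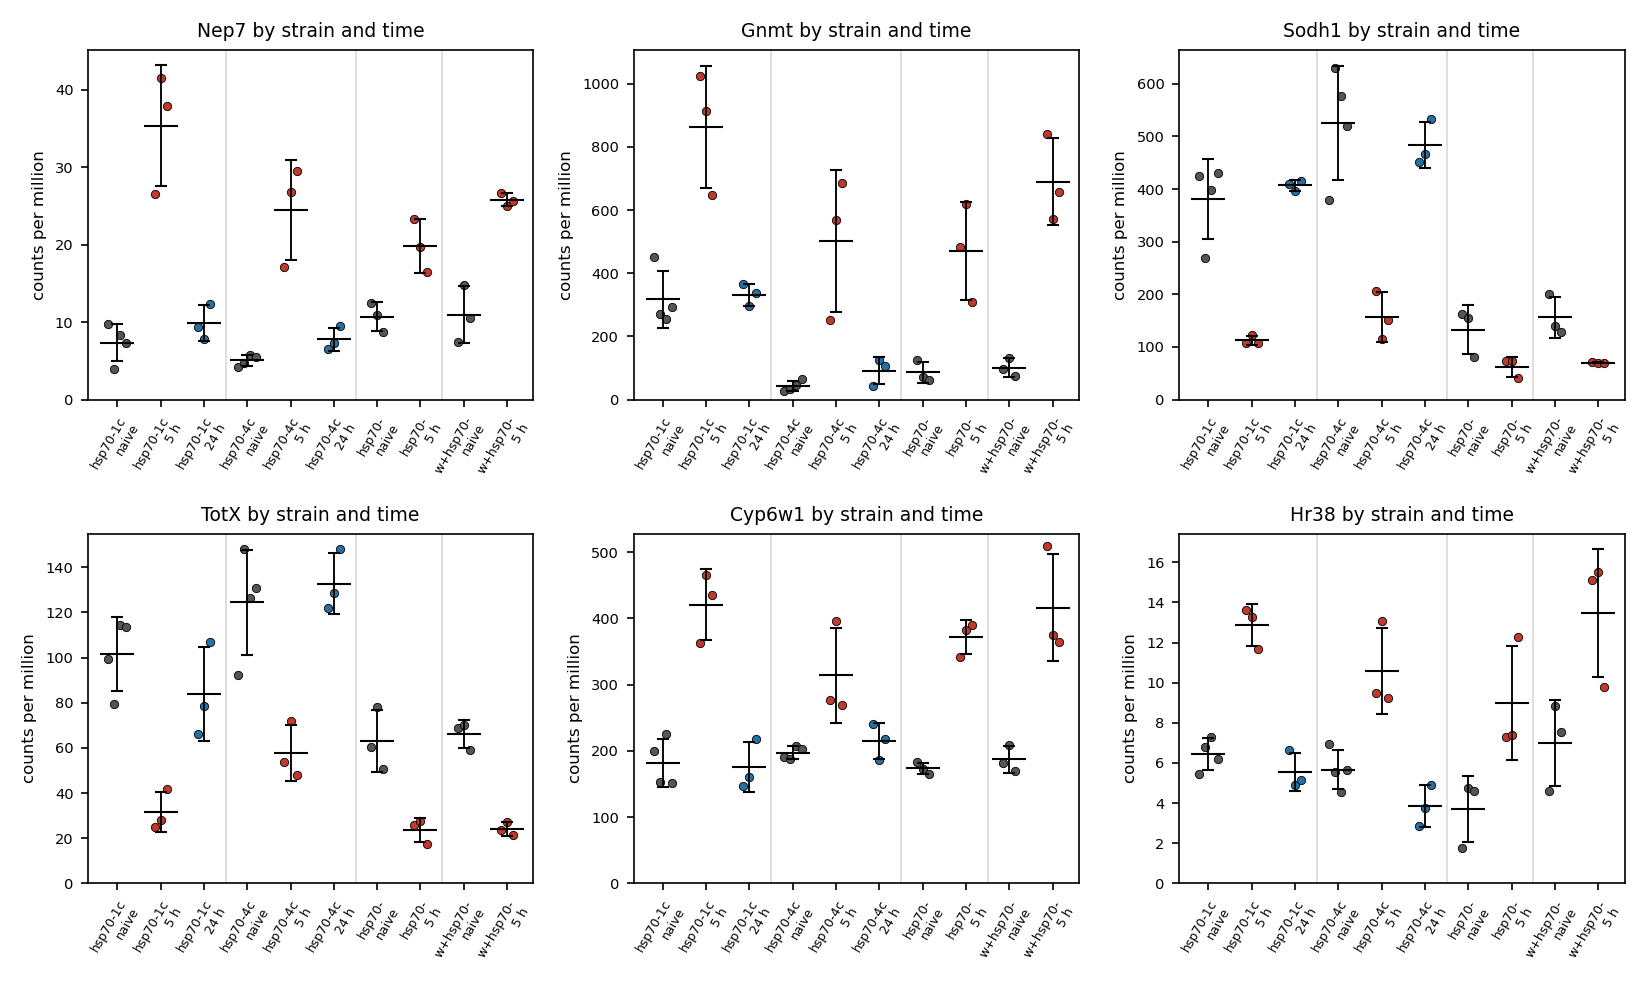
CPM of Nep7, Gnmt, Sodh1, TotX, Cyp6w1 and Hr38 in each library by strain and time. Points are libraries, bars the mean ± SD. In hsp70-1c Nep7 was at 7.36 ± 2.44 in naive flies, 35.3 ± 7.82 at 5 h and 9.89 ± 2.27 at 24 h.

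At 24 h after training in hsp70-4c, 15 of 80 ribosomal protein genes were higher than in naive flies (68 adjusted over the list alone), RpS9 by 0.50 (SE 0.08), with a median of 0.27 (adjusted p = 1.43e-36 and adjusted p = 0.182 with an estimated correlation). Of 25 muscle genes 7 were lower (21 adjusted over the list alone), Mhc by -0.58 (SE 0.09) and Act79B by -0.84 (SE 0.15), with a median of -0.58 (adjusted p = 4.46e-17 and adjusted p = 0.182 with an estimated correlation). In hsp70-4c and hsp70-1c the naive libraries are those of the 5 h comparison, so the results at 24 h and 5 h are not independent. For 24 h against 5 h in hsp70-4c, the ribosomal median was 0.03 and the muscle median -0.02 (camera adjusted p = 0.270 and 0.666). The neuropeptide genes Crz (corazonin) and Hug (hugin) rose by 0.61 (SE 0.12) and 0.42 (SE 0.08). Of 36, 2 were higher (6 higher and 1 lower adjusted over the list alone, adjusted p = 0.000583 and adjusted p = 0.182 with an estimated correlation). Antimicrobial peptides had 1 higher of 22, BomT2 by 0.55 (SE 0.11) (2 adjusted over the list alone, adjusted p = 9.59e-06 and adjusted p = 0.49 with an estimated correlation). Fry passed the ribosomal, muscle and neuropeptide lists (adjusted p = 0.00532, 0.0200 and 0.0217). Of 10400 genes 96 changed, 52 higher and 44 lower, and Hsp70Bc did not pass (log2 change -0.57, SE 0.20, adjusted p = 0.201). The count was 263 without 24h replicate 1, 2 without 24h replicate 2, 0 without 24h replicate 3, 0 without naive replicate 1, 2 without naive replicate 2 and 0 without naive replicate 3, so it rests on single libraries; DESeq2 called 271.

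In hsp70-1c at 24 h no single gene passed in edgeR, with 974 of 10514 at an unadjusted p under 0.05; DESeq2 called 75. Muscle genes had a median of -0.39 (0 called of 25, 17 lower adjusted over the list alone, adjusted p = 2.48e-17 and adjusted p = 0.393 with an estimated correlation), and ribosomal protein genes had 0 called (4 higher adjusted over the list alone, adjusted p = 1.03e-08 and adjusted p = 0.838 with an estimated correlation). Testis genes had a median of 2.23 (0 called of 19, 2 higher adjusted over the list alone, adjusted p = 2.39e-08 and adjusted p = 0.834 with an estimated correlation), with summed levels of 163 and 180 CPM in 24h replicates 1 and 2. Gut enzyme genes had a median of -0.70 (0 called of 48, adjusted p = 0.0146 and adjusted p = 0.969 with an estimated correlation, adjusted p = 0.992 without naive replicate 2, 0.362 without naive replicate 4 and 0.276 without 24h replicate 3).

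Expression at 24 h was also compared directly with that at 5 h, with the same 5 h libraries as above. In hsp70-1c Sodh1 rose by 1.86 (SE 0.15), from 110.9 ± 9.32 to 403.5 ± 4.93 CPM (n = 3 each), TotX by 1.42 (SE 0.23) and AkhR by 0.90 (SE 0.12), while Nep7 changed by -1.82 (SE 0.27), Hr38 by -1.19 (SE 0.16) and Cyp6w1 by -1.25 (SE 0.18). Activity-regulated genes had 4 lower of 16 (adjusted p = 7.97e-06, adjusted p = 0.126 with an estimated correlation and fry adjusted p = 0.00809). In hsp70-4c Sodh1 rose by 1.62 (SE 0.23), and Nep7 changed by -1.66 (SE 0.21), Hr38 by -1.45 (SE 0.22) and the clock gene Pdp1 by -0.58 (SE 0.09). Of 10514 genes in hsp70-1c 143 changed, 92 higher and 51 lower. Of 10400 in hsp70-4c 102 changed, 66 higher and 36 lower. In hsp70-1c the count was 68 without 24h replicate 2, 88 without 5h replicate 1 and 93 without 5h replicate 2, and DESeq2 called 261. In hsp70-4c it was 46 without 24h replicate 1, 9 without 24h replicate 3, 67 without 5h replicate 1, 44 without 5h replicate 2 and 48 without 5h replicate 3, and DESeq2 called 171.

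The 5 h responses of hsp70-4c and hsp70-1c differed in 5 of 10764 genes. The responses of fit, CG9616, CG14400 and CG13563 were higher in hsp70-4c, by 2.59 (SE 0.36), 3.23 (SE 0.47), 1.42 (SE 0.21) and 0.97 (SE 0.17), and that of daw, a TGF-beta ligand gene, was lower, at -1.27 (SE 0.23). The count was 2 without hsp70-1c 5h replicate 2, 9 without hsp70-1c naive replicate 2, and 3 without each of hsp70-1c naive replicate 3, hsp70-4c 5h replicates 2 and 3 and hsp70-4c naive replicates 1, 2 and 3; DESeq2 called 63. Their 24 h responses differed in 0 genes in edgeR (509 at an unadjusted p under 0.05) and 0 in DESeq2. Those of w+hsp70- and hsp70- at 5 h differed in 0 of 10223 genes in edgeR (272 at an unadjusted p under 0.05) and 4 in DESeq2. By camera 6 of 26, 7 of 26 and 4 of 25 lists passed for these differences in the same order, and 0 with an estimated correlation or fry. Between hsp70-4c and hsp70-1c the ribosomal list had a median of 0.21 at 5 h (adjusted p = 7.95e-24 and adjusted p = 0.73 with an estimated correlation). At 24 h, against the same naive libraries, its median was 0.19 (adjusted p = 1.03e-26 and adjusted p = 0.579 with an estimated correlation).

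The mean 5 h response of hsp70- and w+hsp70- differed from that of hsp70-1c and hsp70-4c in 78 of 10843 genes, 31 higher and 47 lower. These p-values too measure variation between replicate pools within strains and not between strains, and strain, genetic background and any batch coincide. Of 80 ribosomal protein genes 8 had a lower response in the hsp70- and w+hsp70- strains (51 adjusted over the list alone), RpS9 by -0.42 (SE 0.09) (adjusted p = 5.76e-30, adjusted p = 0.271 with an estimated correlation and fry adjusted p = 0.0322). The median 5 h change of these genes was 0.25 in hsp70-4c, 0.06 in hsp70-1c, -0.09 in hsp70- and -0.03 in w+hsp70-. The difference thus lies mostly with hsp70-4c and is not a trait of the hsp70- and w+hsp70- strains alone. Of 24 antimicrobial peptide genes 4 had a lower response (5 adjusted over the list alone), BomS1 by -1.03 (SE 0.18) and BomT2 by -0.96 (SE 0.18) (adjusted p = 1.08e-07 and adjusted p = 0.271 with an estimated correlation). Gut enzyme genes had 3 higher of 52 (4 adjusted over the list alone), LManIII by 4.41 (SE 0.87) (adjusted p = 5.02e-09 and adjusted p = 0.562 with an estimated correlation), with summed levels of 36662 CPM in hsp70- 5h replicate 2. The memory gene rut had a lower response, at -1.40 (SE 0.24). Without single libraries the count of genes that differed ran from 25 (w+hsp70- naive replicate 2) to 106 (hsp70- naive replicate 3). It was 44 without hsp70-1c 5h replicate 1, 45 without 5h replicate 2, 48 without 5h replicate 3 and 43 without naive replicate 4 of that strain; 39, 51 and 39 without hsp70-4c 5h replicates 1, 2 and 3 and 43 and 46 without its naive replicates 1 and 3. It was 49, 42 and 44 without w+hsp70- naive replicate 1 and 5h replicates 1 and 3, and 47 and 45 without hsp70- naive replicate 1 and 5h replicate 1; DESeq2 called 193.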

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

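The tests of called pairs 10 to 20 genes apart, of the muscle share (for the 42 genes and in hsp70-4c), of reads outside genes for the 42 genes and of the SE with the clock index were chosen only after the results were seen; the other tests of this part were chosen before. Values in 88 groups of 4 naive libraries were compared for a library far from the rest, 8 were past the critical value for 4 samples, and chance alone gives about 5 percent. In the naive hsp70-1c group, replicate 3 stood apart for Hsp70Bc (0.309 CPM against 0 in the others; gap over range 1) and for Octbeta3R (0.103 against 0; 1). These rest on 3 counts and 1 count, and gap over range is 1 wherever the other libraries are at 0, so both say nothing. In the same group replicate 2 stood apart for BomS1 (448 against 566 in the nearest, gap over range 0.849). Replicate 4 stood apart for the list of protein-coding genes of the mitochondrial genome (51432 against 76888, gap over range 0.907). In the naive hsp70-4c group, replicate 2 stood apart for VhaM9.7-c (37.7 against 33.2; 0.882) and for the activity-regulated (707 against 731; 0.921), chaperone (3471 against 3196; 0.9005) and chemoreceptor (480 against 538; 0.912) lists. The 5 h response differed between hsp70-4c and hsp70-1c in 5 genes, and between the mean of hsp70- and w+hsp70- and that of hsp70-1c and hsp70-4c in 78. Reads outside annotated genes made up a median of 65.3% over the 32 libraries, a share that depends on the strand setting of the counting, which is not stated.

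The first pattern is the 42 genes that changed the same way at 5 h in 3 or more strains. An index of clock genes was higher at 5 h than in naive flies by 2.46, 1.19 and 1.10 in hsp70-1c, hsp70-4c and w+hsp70-, and at 24 h it was -1.34 to -0.48 in hsp70-1c and -0.67 to 0.04 in hsp70-4c against -1.90 to 0.40 and -0.36 to 1.11 in naive flies, which goes with a different clock time of collection. In hsp70- it was not higher at 5 h (0.39 ± 0.04 against 0.90 ± 0.57), while 41 of the 42 genes had the same direction there (median directed change 0.58, median absolute deviation 0.32). By what was written beforehand, clock time is argued against as the whole cause. With the index as covariate in the other strains, the median directed change of the 42 was at least 1.07 times that without it. It was 0.91, 0.91 and 0.78 against 0.85, 0.79 and 0.72 in hsp70-1c, hsp70-4c and w+hsp70- (median absolute deviations with the index 0.46, 0.28 and 0.42). Fewer of the 42 then passed the test (23, 37 and 2, against 42 in each without it). Their median SE rose from 0.12, 0.13 and 0.11 to 0.21, 0.15 and 0.24, by a median factor of 1.82, 1.31 and 2.33 per gene. The overlap of the index with the groups gives a factor of 1.89, 1.37 and 2.14 by the design alone. The calls thus ended with a larger SE and not with a smaller change. With this overlap the slope of the index is imprecise and the covariate is a weak test, most so in w+hsp70-. The 42 genes were also picked from these same libraries. Their median directed change was only 0.12 at 24 h in hsp70-1c and 0.17 in hsp70-4c, which clock time would also give. The argument against clock time thus rests mainly on hsp70-. A clock index rises and falls over the day, so an index that is not higher there can still come from a different clock time. Clock time thus stays open. A smaller share of muscle tissue in trained heads is argued against by a median directed change of 0.17 at 24 h in hsp70-4c. All 25 muscle genes had a negative log2 change there too, with 7 called (camera adjusted p = 0.182 with an estimated correlation). A larger share of reads outside genes in naive libraries is argued against by a median directed change of 0.12 at 24 h in hsp70-1c. The response to training, with handling and any social contact it involved, also stays open and is a hypothesis only.

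The second pattern is the lower expression of muscle genes in trained hsp70-4c flies. A larger share of reads outside genes in naive libraries needs a positive correlation between that share and the muscle level. Over 20 libraries, deviations from group means had a Pearson r of -0.345 (permutation p = 0.227) and a Spearman rho of -0.227 (permutation p = 0.421), and r was -0.239 without the 2 farthest libraries. These have the opposite sign, but none passed, so the share is not excluded. A smaller share of muscle tissue in the sampled heads stays open: 100% of the 25 muscle genes had a negative log2 change at both 5 h and 24 h (11 and 7 called), but that was known when the test was chosen and does not support it. Lower transcription of muscle genes as a set would give the same values, so these cannot be told apart here. Both times were compared with the same naive libraries, so their agreement is partly built in. For 24 h against 5 h the median log2 change of the muscle genes was -0.02 (camera adjusted p = 0.666).

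The third pattern is the position of the genes that differ between naive strains. Neighbouring called pairs were 2.17 times the mean of 10000 shufflings between hsp70-4c and hsp70-1c, which meets what was written beforehand for segments that differ between the strains (more than 1.44, the ratio of the 5 h calls in hsp70-4c). It was not read so, because the 5 h calls of hsp70-1c and w+hsp70-, which compare flies of the same strain, gave 2.14 and 3.24. For hsp70- and w+hsp70- against hsp70-1c and hsp70-4c the ratio was 1.41 (permutation p = 1e-04), just below 1.44, a bound that came from 44 pairs, so it decides nothing. Between w+hsp70- and hsp70- it was 12.6, from 1 pair (permutation p = 0.0767). Between hsp70-4c and hsp70-1c, pairs 10 to 20 genes apart were 1.18 times the shuffled mean (permutation p = 1e-04, the smallest possible), above the highest ratio of the 5 h calls (1.14). For hsp70- and w+hsp70- against hsp70-1c and hsp70-4c the ratio was 1.03 (permutation p = 0.0229), below 1.14. By the bound first set these would speak for long segments of different origin in the former comparison and against them in the latter. That bound came from 50 pairs (permutation p = 0.195) with an SD of 0.147 over shufflings, and both ratios lie within it, so after the values were seen both were left as not decided.

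Other splits of the same libraries test whether chance could give as many calls. At 5 h, 1 of 35 splits called as many genes as the real one in hsp70-1c (real 369, highest other 9) and 1 of 35 in hsp70-4c (570; 6). The share was the same for naive hsp70-4c against hsp70-1c (1 of 35; 1058; 1). Chance can be excluded at this level, the smallest that 35 splits allow, without adjustment over the comparisons. At 24 h in hsp70-4c the share was also 1 of 35 (96; 28). The count there fell to 0 without 24h replicate 3, so chance is not called excluded. For the naive hsp70- and w+hsp70- strains against the others (1 of 100; 1610; 918) all strain labels were shuffled. For their 5 h responses (1 of 50; 78; 0) training labels were shuffled within each strain. Other differences break these shuffles too, so they do not exclude chance for these contrasts. Chance cannot be excluded for the 5 h responses of hsp70-4c against hsp70-1c (5 of 100; 5; 45). Where edgeR called 0 genes every split gives as many, so the splits say nothing about chance. This holds for hsp70-1c at 24 h (35 of 35; highest other 8; 974 genes at an unadjusted p under 0.05, DESeq2 75). It also holds for the 24 h responses of hsp70-4c against hsp70-1c (100 of 100; 21; 509, DESeq2 0) and the 5 h responses of w+hsp70- against hsp70- (100 of 100; 43; 272, DESeq2 4). The splits are too few for a share under 0.05 in w+hsp70- at 5 h (1 of 10, real 193, highest other 5). They are also too few for 24 h against 5 h in hsp70-1c (1 of 10, 143, 12) and hsp70-4c (1 of 10, 102, 14). In hsp70- at 5 h (3 of 10, 3, 6) and naive w+hsp70- against hsp70- (2 of 10, 30, 241) another split called more genes than the real one. The calls of both thus do not exceed what other splits of the same libraries give. The split calling 241 genes points to a structure of the samples, which was not identified.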

How the results depend on the processing

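All alternatives were chosen before the data were examined. Of 334 values of genes named by the rule, 319 were past the threshold. Of these, 190 stayed past it in every fit without 1 library and 240 in every other alternative, and 0 reversed. With DESeq2 size factors 329 of 334 kept their side, with no filter 315, with the replicate block 296, with all 32 libraries 260 of 313 and with the DESeq2 Wald test 304 of 313. Size factors moved the share of higher calls by up to -4.03 points. Whether replicate numbers of the titles pair the samples was not decided: of 24 same-number pairs 10 correlated above 0.1, from -0.187 to 0.477. Pairs of 24 h and 5 h libraries had -0.005, 0.254 and 0.318 in hsp70-1c and 0.477, 0.002 and 0.274 in hsp70-4c. These were not compared with pairs of different numbers, so batches shared between groups stay open. The deposited files number some libraries of hsp70- and naive hsp70-4c otherwise, and pairs by those numbers were not tested. Several counts of changed genes moved, and the cause was not tested. With no filter the count was 22 in hsp70- and 468 in w+hsp70- at 5 h and 1 in hsp70-1c at 24 h. It was then 1 for the responses of w+hsp70- against hsp70- and 45 for those of both against hsp70-1c and hsp70-4c. With all 32 libraries it was 76 in hsp70- and 107 in w+hsp70- at 5 h, 10 in hsp70-1c and 220 in hsp70-4c at 24 h, and 2 for the 5 h responses of hsp70-4c against hsp70-1c. With the replicate block it was 28 in hsp70- at 5 h, 281 in hsp70-4c at 24 h, and 13 and 2 for the 5 h responses of hsp70-4c against hsp70-1c and of w+hsp70- against hsp70-. With DESeq2 it was 39 in hsp70- at 5 h, 75 and 271 in hsp70-1c and hsp70-4c at 24 h, and 261 and 171 in them for 24 h against 5 h. It was then 48 for naive w+hsp70- against hsp70-, and 63, 4 and 193 for the differences of 5 h responses. Lists past the threshold (10, 4, 9, 3, 4 and 8 in the 6 comparisons) fell to 0 in each with an estimated correlation. With fry they were 2 in hsp70-1c, 5 in hsp70-4c, 0 in hsp70- and 0 in w+hsp70- at 5 h, and 0 and 3 in hsp70-1c and hsp70-4c at 24 h.

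Without 1 library at a time, calls at 5 h ranged from 180 to 383 in hsp70-1c, 205 to 464 in hsp70-4c, 0 to 17 in hsp70- and 95 to 253 in w+hsp70-. They ranged from 0 to 263 in hsp70-4c at 24 h, and from 68 to 109 and 9 to 69 for 24 h against 5 h in hsp70-1c and hsp70-4c. For naive strains they ranged from 793 to 1005 (hsp70-4c and hsp70-1c), 12 to 52 (w+hsp70- and hsp70-) and 1279 to 1995 (both against the others). For differences of responses they ranged from 2 to 9, 0 to 1, 0 to 0 and 25 to 106. Lists past the threshold ranged from 7 to 11, 3 to 6, 5 to 9 and 3 to 7 at 5 h, and from 3 to 7 and 6 to 8 at 24 h. In hsp70-, without naive replicate 1, the memory and synaptic lists reversed (adjusted p = 0.535 and 0.722), and their lowest values, without naive replicate 3, were 0.000176 and 0.00361. The Hsp70 log2 difference ranged from 2.30 to 2.47 for hsp70-4c against hsp70-1c, and from -1.61 to -1.20 for hsp70- and w+hsp70- against both. Depth limits the rarer transcripts, such as the 6 Hsp70 genes, which summed to 0 to 4 counts in each library other than those of hsp70-4c.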

Other observations

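No test in this part was chosen after the results were seen. At 24 h in hsp70-4c, 4 further lists passed with 0 genes called in each by edgeR. Synaptic genes had a median log2 change of -0.18, with 2 of 22 lower adjusted over the list alone (adjusted p = 0.000492 and adjusted p = 0.638 with an estimated correlation). Without 24h replicate 1 the adjusted p was 0.0987. The cAMP and memory genes had a median of -0.11, with 1 higher and 1 lower of 48 adjusted over the list alone (adjusted p = 0.0103 and adjusted p = 0.723 with an estimated correlation). It was 0.742 without 24h replicate 1 and 0.128 without naive replicate 4. Chemoreceptor genes had a median of -0.17 (adjusted p = 0.0387 and adjusted p = 0.258 with an estimated correlation). It was 0.0987 and 0.0865 without 24h replicates 1 and 3 and 0.0664 without naive replicate 3. Detoxification genes had a median of 0.06 (adjusted p = 0.0319 and adjusted p = 0.676 with an estimated correlation). It was 0.409 and 0.0789 without 24h replicates 1 and 3, and 0.0664 and 0.0596 without naive replicates 1 and 2.

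At 5 h in hsp70- the remaining lists that passed had 0 genes called in each by edgeR. Ribosomal protein genes had a median of -0.09 (adjusted p = 0.000417 and adjusted p = 0.858 with an estimated correlation). It was 0.660 without naive replicate 1 and 0.487 without 5h replicate 3. Other chaperones had a median of 0.11 (adjusted p = 0.0285 and adjusted p = 0.529 with an estimated correlation). It was 0.0978 and 0.283 without naive replicates 2 and 3 and 0.0580 without 5h replicate 1. Phototransduction genes had a median of -0.11 (adjusted p = 0.0313 and adjusted p = 0.529 with an estimated correlation). It was 0.114 without naive replicate 1, and 0.259 and 0.0529 without 5h replicates 1 and 2. Activity-regulated genes had a median of 0.10, with 3 of 15 higher adjusted over the list alone (adjusted p = 0.0406 and adjusted p = 0.529 with an estimated correlation). It was 0.431 and 0.114 without naive replicates 1 and 2, and 0.0529 and 0.201 without 5h replicates 2 and 3.

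Some lists had a median, mean and test that differed in sign, none past the threshold. In hsp70-1c at 5 h immune signalling genes had a median of -0.01 and a mean of -0.19 with a test pointing up. Protein-coding genes of the mitochondrial genome there had a median of -0.02 and a mean of -0.05 with a test pointing up. In hsp70- at 5 h antimicrobial peptides had a median of -0.09 and a mean of 0.37 with a test pointing down. The large mitochondrial ribosomal RNA took 9.09% to 15.3% of assigned reads in a library.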
